A study of Mus musculus with 4 samples.

How the data were processed

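Polyadenylated RNA was sequenced from R1 mouse embryonic stem cells, a male line, in 2 groups: control cells, labelled wild type, and cells labelled Usp28 KO (knockout), with 2 libraries each. Per the labels' protocols, the cells grew on 0.2% gelatin in N2B27 with the MEK inhibitor PD0325901 at 1 μM, the GSK3 inhibitor CHIR99021 at 3 μM and leukaemia inhibitory factor (LIF) at 10 ng/ml, the condition known as 2i/LIF. Libraries were made from 1 μg of total RNA with an integrity number of at least 6.5, by oligo(dT) selection and an Illumina TruSeq RNA kit.

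The deposited table holds raw read counts per gene, with the exon positions of each gene in the layout that featureCounts writes. HISAT2, featureCounts, DESeq2 and the mm10 build are named, without versions, in the submitters' processing notes. The strand setting, the treatment of reads that match several places and the annotation release are not given in the sources used here. Near-identical genes (the class I histocompatibility genes, the Zscan4 cluster, heat shock genes Hspa1a and Hspa1b, ribosomal protein genes with processed pseudogenes), overlapping genes and antisense partners such as Xist and Tsix are therefore uncertain. The table has 55401 genes, and all columns belong to the 4 libraries. Gene symbols and transcript GC content came from GENCODE M21: 55141 identifiers matched without their version suffix and 260 did not, and all 54349 that matched with the suffix had the same coordinates. Positions are those of the deposited table, on mm10, and give the span of all annotated exons of a gene. No row without a gene was present.

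Counts were analysed in R 4.3.3. The main test was edgeR 4.0.16: genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 15341; libraries were scaled by the trimmed mean of M values (TMM); and a robust quasi-likelihood fit compared Usp28 KO with control, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are Usp28 KO minus control, from the quasi-likelihood fit with its standard errors unless DESeq2 is named. Gene values are reads per 1e6 counts (CPM) of the library total after the filter times its TMM factor, and are means ± SD over n = 2 libraries per group. Gene lists were tested with camera in limma 3.58.1 on voom-transformed values with the preset inter-gene correlation of 0.01, adjusted over the 34 lists with at least 5 tested members of 35 lists drawn up. Chromosomes were tested the same way. An estimated correlation, used as an alternative, rests on the few residual degrees of freedom of 2 libraries per group. Its power was not measured, so a call lost under it does not decide the question. Within each list the gene-level p was also adjusted over the list alone. This second adjustment does not account for the number of lists, and some genes are in several lists. The labels do not say whether the libraries of a group came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical.

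The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took Usp28; the 10 genes with the largest fold change each way and the 5 with the smallest adjusted p each way, among genes at adjusted p under 0.05 by edgeR with a mean of at least 5 CPM, groups that did not overlap and a symbol that is not a predicted or clone name; up to 4 members of each list by smallest p; and 24 fixed genes. No gene reached the edgeR threshold, so the second part named none. The same rule was applied instead to the calls of DESeq2 1.42.0, a step added after the values were seen, and those genes are named with their DESeq2 p. The members Pgk1, Gpi1, Gdf3, Cldn3, Bst2 and Irf9, and the genes used to follow up the Y chromosome, were also chosen after their values were seen.

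The alternatives were DESeq2, limma-voom, glmTreat against a 1.5-fold change, DESeq2 size factors, upper-quartile scaling, library totals without scaling factors, no filter, a filter of 50 counts in 2 libraries, removal of 52 genes (the mitochondrially encoded genes and the 20 most abundant), a replicate block, leaving out each library in turn, and for lists camera with an estimated correlation and fry. A correction for GC content, alone and with the replicate block, was chosen after seeing the data: offsets took up a smooth trend (natural spline, 5 degrees of freedom) of log CPM on transcript GC content in each library, which was known for 99.9% of the tested genes.

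The steps were tested on simulated counts with the means and library sizes of the real data. Of 50 genes changed at each size, edgeR recovered 18% at 1.5-fold, 74% at 2-fold, 100% at 3-fold and 98% at 4-fold, with 7 false calls among 15341 genes. DESeq2 recovered 22%, 84%, 100% and 98%, with 16 false calls. A simulated list of 30 genes shifted 1.5-fold was called, and 0 of 34 random lists were. Genes were simulated independently of each other, without a GC trend, so this does not test list calls where members vary together. Total counts were 16595196 to 19533608 per library, so 1 read is 0.0512 to 0.0603 CPM of the library total. A count of 0 allows up to 3 counts, or 0.154 to 0.181 CPM in a library. These limits and the intervals given for read ratios cover counting error only, since reads without molecular identifiers are not independent molecules.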

Results

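The data compare gene expression in mouse embryonic stem cells with and without a targeted Usp28 gene, under 2i/LIF culture. Usp28 encodes a deubiquitinase that removes ubiquitin from substrates of the FBXW7 ubiquitin ligase, MYC among them. The control group and the Usp28 KO group had 2 libraries each. Control replicates 1 and 2 held 19533608 and 16595196 counts, and Usp28 KO replicates 1 and 2 held 17996611 and 18709558. Between 22304 and 22810 genes had at least 1 read in a library. Across genes, which are not independent replicates, log2 CPM values correlated at r = 0.985 between the control replicates, r = 0.985 between the Usp28 KO replicates and r = 0.976 to 0.984 between libraries of different groups. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 30.2 for the control pair and 28.2 for the Usp28 KO pair.

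The targeted gene, Usp28 (ENSMUSG00000032267, chromosome 9, 48985375 to 49042517), kept its read count in the libraries labelled Usp28 KO. It had 3690 and 3120 counts in the control libraries, and 3392 and 3319 in the libraries labelled Usp28 KO. This was 193 ± 5.56 CPM in control and 179 ± 3.13 CPM in Usp28 KO libraries, a log2 fold change of -0.11 ± 0.15 (edgeR, adjusted p = 0.857). A knockout made by a small edit can leave the amount of transcript as it was, and the table gives no counts per exon. The gene-level count therefore does not check the label, and every direction below is between libraries as labelled. The related deubiquitinase gene Usp25 stood at 18.96 ± 1.13 CPM in control and 18.97 ± 2.23 CPM in Usp28 KO libraries (log2 fold change -9.5e-05 ± 0.21).

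By DESeq2, Myc fell from 9.79 ± 0.119 to 3.04 ± 1.35 CPM in the libraries labelled Usp28 KO (adjusted p = 0.00461), and the ETS factor gene Etv4 fell from 10.8 ± 2.17 to 3.63 ± 0.597 CPM (adjusted p = 0.00267). Ddit4, which encodes an inhibitor of mTORC1, rose from 87.98 ± 18.2 to 219 ± 35.9 CPM (DESeq2, adjusted p = 5.68e-06). Dppa3, a gene of the early embryo and germ line, rose from 5.03 ± 1.90 to 15.7 ± 2.41 CPM (DESeq2, adjusted p = 0.000716). The neuronal enolase gene Eno2, the intermediate filament gene Nes and the growth factor binding protein gene Igfbp2 rose by 1.36, 1.25 and 0.96 on the log2 scale by DESeq2. None of these passed the edgeR test. Myc and Igfbp2 were also not among the genes that edgeR called in every fit with a library left out. The Myc log2 fold change ranged from -2.23 to -1.29 in those fits.

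By edgeR, 0 of 15341 genes were higher and 0 lower at an adjusted p under 0.05. The lowest adjusted p was 0.0540, shared by 8 genes, and 58 genes were under 0.1, of which 39 were higher and 19 lower. Of those 8, Ddit4, Eno2 and Nes had an adjusted p of 0.299 by edgeR after GC correction. Their log2 fold changes were then 1.16, 1.27 and 1.15, against 1.32, 1.37 and 1.26 before. At an unadjusted p under 0.05 edgeR counted 1052 genes higher and 666 lower, where 767 in all were expected with no difference. DESeq2 called 79 genes higher and 48 lower among 13668 with an adjusted p (671 and 555 at an unadjusted p), and limma-voom called 0 each way (1049 and 657 unadjusted). With the replicate number as a block, edgeR called 965 genes higher and 716 lower, in place of 0 each way. The labels do not say whether same-numbered libraries share a batch. For all 127 genes called by DESeq2 the groups did not overlap, which held for 41.8% of the tested genes and is 33.3% by chance. With 2 libraries per group a low p favours such genes, so this is not separate support for the calls. The edgeR count moved when a library was left out: 49 higher and 94 lower without control replicate 1, 125 and 38 without control replicate 2, 111 and 31 without Usp28 KO replicate 1, and 146 and 200 without Usp28 KO replicate 2. Some genes were called in all 4 of these fits, and DESeq2 also called each of those. The 4 fits share libraries with each other and with the DESeq2 test, so this is not independent support.

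Besides those above, the genes with the largest DESeq2 increases, among those averaging at least 5 CPM, were Got1l1 (chromosome 8, 27197459 to 27223828; 3.60 ± 0.610 to 14.03 ± 2.48 CPM), Pacsin1, Kif1a, Bhlhe41, Cldn7, Fos, Tspan7, Greb1l and the class I histocompatibility gene H2-Bl, which shares sequence with its paralogs. Their DESeq2 log2 fold changes ran from 1.42 for Greb1l to 1.96 for Got1l1. The largest DESeq2 decreases among genes at that level, besides Myc and Etv4, were in Lgals3, Id3, Sh2d4b, Spry4, Trpm1, Zmat4, Cdx1 and Plagl1, between -1.38 for Plagl1 and -1.62 for Lgals3. Among the decreases with the smallest p, Sfr1 fell from 139 ± 31.9 to 58.1 ± 9.62 CPM and Enox1 from 86.8 ± 0.748 to 39.9 ± 5.77 CPM (DESeq2, adjusted p = 4.23e-05 and 5.1e-05). Their edgeR adjusted p was 0.0540 in each case.

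**Figure D1:**
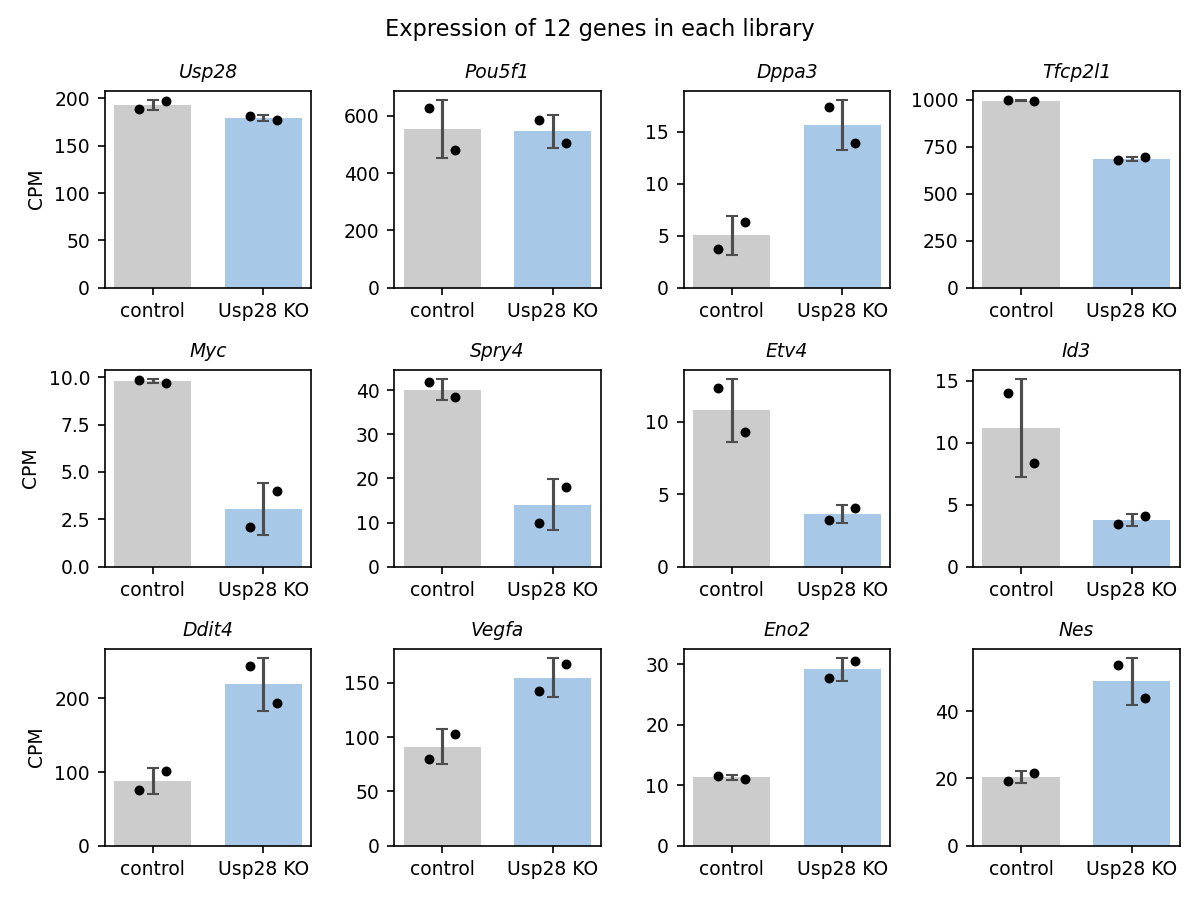
Expression of 12 genes, in CPM (linear axes from 0), in control (grey) and Usp28 KO (blue) libraries. Bars are means, error bars are SD, and points are the 2 libraries of each group. Pou5f1 lies within about the same range in both groups and Usp28 is slightly lower in the Usp28 KO libraries, while Ddit4 rises from 87.98 to 219 CPM and Myc falls from 9.79 to 3.04 CPM.

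The lists of hypoxia response and glycolysis genes were higher in the libraries labelled Usp28 KO. The hypoxia response list had a median log2 fold change of 0.56 over 26 tested members (camera, adjusted p = 4.84e-11; adjusted p = 0.796 with an estimated correlation). Adjusted over the list alone, 11 members were higher, 1 lower and 14 not past the test; over all genes 0 were. Ddit4, Ndrg1, P4ha2 and Vegfa rose by 1.32, 1.01, 1.09 and 0.76, and Vegfa, the vascular growth factor gene, went from 91.2 ± 16.4 to 155 ± 18.1 CPM (list-alone adjusted p = 0.00553). The glycolysis list had a median of 0.40 over 24 members (camera, adjusted p = 4.84e-11; adjusted p = 0.796 with an estimated correlation), with 6 higher, 0 lower and 18 not past the test adjusted over the list alone. These were Eno2, the lactate transporter gene Slc16a3 (109.7 ± 7.41 to 179.9 ± 16.1 CPM), Pfkfb3, Aldoc, Pgk1 and Gpi1. Neither list lost the camera call when any library was left out; the hypoxia median was 0.32 without control replicate 1.

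Core pluripotency genes differed between the groups by less than their standard errors, and 2 of 20 naive pluripotency genes fell adjusted over their list alone. Pou5f1 was at 554 ± 102 CPM in control and 546 ± 58.02 CPM in Usp28 KO libraries (log2 fold change -0.020 ± 0.18), Sox2 differed by 0.050 ± 0.17 and Nanog by -0.11 ± 0.18. The naive pluripotency list had a median log2 fold change of -0.31 over 20 members (camera, adjusted p = 0.00127; adjusted p = 0.796 with an estimated correlation). Adjusted over the list alone, Dppa3 was higher, Gbx2 and Tfcp2l1 were lower, and 17 did not pass. Tfcp2l1, a naive-state transcription factor, fell from 996 ± 3.29 to 687 ± 9.87 CPM (list-alone adjusted p = 0.0468), and Gbx2 fell from 31.8 ± 6.12 to 18.1 ± 2.23 CPM. Tcl1, Zfp42, Esrrb and Klf4 had log2 fold changes of -0.53, -0.33, -0.16 and 0.11, and none passed. The list median was -0.18 without control replicate 2 (adjusted p = 0.109) and -0.12 without Usp28 KO replicate 1 (adjusted p = 0.326).

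The general pluripotency list had a median of -0.11 (camera, adjusted p = 0.0746) with 0 of 20 members past the list-alone test. Its adjusted p was 0.796 with an estimated correlation. Its median was -0.20 after GC correction (adjusted p = 0.0454), -0.16 without control replicate 1 (adjusted p = 0.102) and -0.24 without Usp28 KO replicate 2 (adjusted p = 0.0274). L1td1, an RNA-binding protein gene of stem cells, fell from 747 ± 19.8 to 493 ± 37.2 CPM by DESeq2 (adjusted p = 0.0467), while Gdf3, Zfp281 and Dppa2, at -0.46, -0.45 and -0.62, did not pass it. The formative and primed pluripotency list had a median of 0.059 (adjusted p = 0.896), with Lefty1 and Lefty2 lower and 20 members not past the list-alone test. Otx2 and Dnmt3b had log2 fold changes of 0.062 ± 0.24 and -0.15 ± 0.18. Fgf5 was near the detection limit, at 0.191 ± 0.0918 CPM in control and 0.0534 ± 0.000111 CPM in Usp28 KO libraries. The 2-cell-like list had a median of -0.037 over 9 members (adjusted p = 0.888), with 0 past the list-alone test. Zscan4c, at -0.037, and Zscan4d, at 0.65, share sequence with the other Zscan4 copies.

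Members of the ERK pathway's target list moved in opposite directions. Etv1, Spry4, Etv4 and Myc fell and Ier3 and Fos rose, adjusted over the list alone, and 15 of 21 did not pass. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, went from 40.1 ± 2.42 to 14.04 ± 5.79 CPM (list-alone adjusted p = 0.000649), and Etv1 from 17.8 ± 1.07 to 7.24 ± 0.174 CPM. Ier3 rose from 7.28 ± 1.47 to 19.02 ± 4.35 CPM. The list median was -0.13 (camera, adjusted p = 0.407), and 0.017 without control replicate 1. Among LIF and STAT3 targets, Ier3 and the adhesion gene Icam1 rose and Gbx2 and Tfcp2l1 fell adjusted over the list alone, and 18 did not pass (median 0.033, adjusted p = 0.506). Among WNT targets, the caudal factor gene Cdx1 fell from 8.02 ± 0.1004 to 2.99 ± 0.825 CPM (list-alone adjusted p = 0.00777), 19 others did not pass, and the list median was -0.070 (adjusted p = 0.888).

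The Notch list was higher, with a median log2 fold change of 0.43 over 14 members (camera, adjusted p = 0.0155; adjusted p = 0.796 with an estimated correlation). The ligand genes Dll1 (1.19 ± 0.0955 to 4.92 ± 0.690 CPM) and Jag2 (25.8 ± 7.03 to 51.9 ± 11.3 CPM) and the target Hey2 rose and Id3 fell, adjusted over the list alone, and 10 did not pass. Notch1 itself had a log2 fold change of 0.30 ± 0.16 (edgeR, adjusted p = 0.538), and of 0.15 after GC correction. The Notch median was 0.23 after GC correction (adjusted p = 0.0727), 0.31 without control replicate 2 (adjusted p = 0.288) and 0.19 without Usp28 KO replicate 2 (adjusted p = 0.0580). In the list of TGF-beta, nodal and BMP targets, 5 members fell, 1 rose and 18 did not pass, adjusted over the list alone. Id3, Lefty1, Lefty2 and Gdf3 were among those that fell, and the phosphatase gene Dusp9 rose. Lefty2, a nodal antagonist, went from 330.1 ± 15.4 to 201 ± 25.5 CPM (list-alone adjusted p = 0.0105). That list's median was -0.20 (adjusted p = 0.0746; adjusted p = 0.796 with an estimated correlation). It was -0.35 after GC correction (adjusted p = 0.0386), -0.041 without Usp28 KO replicate 1 (adjusted p = 0.330) and -0.41 without Usp28 KO replicate 2 (adjusted p = 0.0187).

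Among genes tied to USP28 and FBXW7 through their protein products, Myc fell and Jun rose, and 22 of 24 did not pass the test adjusted over the list alone. Jun went from 8.78 ± 1.49 to 18.2 ± 4.91 CPM (list-alone adjusted p = 0.0153; DESeq2, adjusted p = 0.0483). Mycn, the more abundant MYC-family transcript here, was at 205 ± 12.3 CPM in control and 195 ± 12.3 CPM in Usp28 KO libraries (log2 fold change -0.071 ± 0.16). Over all settings the Mycn log2 fold change ran from -0.17 to -0.0091. Ccne1, Fbxw7, Trp53 and Hif1a had log2 fold changes of -0.024, -0.30, -0.33 and -0.50, and none passed. The list median was -0.056 (camera, adjusted p = 0.269), -0.0091 without Usp28 KO replicate 1 (adjusted p = 0.763) and -0.11 without Usp28 KO replicate 2 (adjusted p = 0.0580).

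MYC targets were slightly lower as a set, with a median of -0.16 over 48 members (camera, adjusted p = 0.0155; adjusted p = 0.796 with an estimated correlation). None of the 48 passed adjusted over the list alone; the genes Nop58, Utp20, Ranbp1 and Npm1, with the smallest p, lay between -0.40 and -0.31. The call ended with library totals in place of TMM (-0.10, adjusted p = 0.0531), without control replicate 1 (-0.075, adjusted p = 0.301) and without Usp28 KO replicate 2 (-0.16, adjusted p = 0.0576). Cytosolic ribosomal protein genes were higher, with a median of 0.18 over 67 members (camera, adjusted p = 0.000157; adjusted p = 0.796 with an estimated correlation). Rps28, Rps29, Rps20 and Rplp2 had log2 fold changes of 0.49, 0.61, 0.37 and 0.49, and 0 of 67 passed alone. With a library left out, Rps29 ranged from 0.16 to 0.95 and Rplp2 from 0.079 to 0.81. The ribosomal median was 0.34 without control replicate 1 (adjusted p = 1.53e-08), 0.055 without control replicate 2 (adjusted p = 0.614), 0.011 without Usp28 KO replicate 1 (adjusted p = 0.930) and 0.36 without Usp28 KO replicate 2 (adjusted p = 3.88e-12).

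Mitochondrially encoded transcripts were lower, with a median log2 fold change of -0.84 over 15 members (camera, adjusted p = 8.43e-07; adjusted p = 0.796 with an estimated correlation). The large ribosomal RNA mt-Rnr2 fell from 657 ± 244 to 358 ± 32.04 CPM (list-alone adjusted p = 0.0394) and 14 members did not pass; mt-Co1 had a log2 fold change of -0.62 ± 0.31. Mitochondrial genes took 2.77% and 5.65% of the counts in control replicates 1 and 2, and 1.92% and 3.33% in Usp28 KO replicates 1 and 2. With a library left out, mt-Rnr2 ranged from -1.21 to -0.45 and mt-Co1 from -0.996 to -0.12. The list median was -1.35 without control replicate 1 (adjusted p = 1.9e-14), -0.082 without control replicate 2 (adjusted p = 0.328), -0.49 without Usp28 KO replicate 1 (adjusted p = 2.21e-07) and -1.44 without Usp28 KO replicate 2 (adjusted p = 3.76e-34), and after GC correction it was -0.50 (adjusted p = 0.00819). Nuclear oxidative phosphorylation genes had a median of 0.10 (adjusted p = 0.109), with 0 of 35 past the list-alone test. That median was 0.21 without control replicate 1 (adjusted p = 0.00108), 0.017 without control replicate 2 (adjusted p = 0.737), 0.23 without Usp28 KO replicate 2 (adjusted p = 0.00103) and -0.062 without Usp28 KO replicate 1 (adjusted p = 0.587). Libraries also differed in how expression depended on transcript GC content. Each library's log2 CPM, against the mean of the other libraries, was rank-correlated with GC content across genes. The correlation was 0.0555 and -0.441 in control replicates 1 and 2, and 0.0031 and 0.451 in Usp28 KO replicates 1 and 2. Across 10701 genes averaging at least 5 CPM, the log2 fold change between the groups correlated with GC content at 0.323. Between same-numbered libraries this was -0.028 for number 1 and 0.599 for number 2. For the groups it was -0.055 after GC correction. The comparison of the groups without that correction is therefore mixed with a GC trend.

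**Figure D2:**
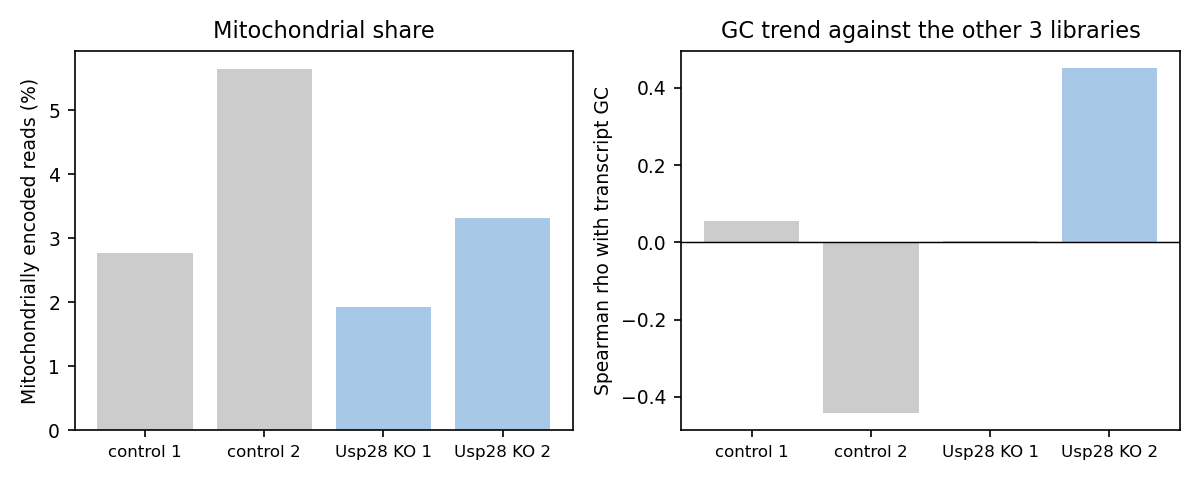
Left, the percentage of counts from mitochondrially encoded genes in each of the 4 libraries (bars, axis from 0). Right, the Spearman correlation across genes between transcript GC content and each library's log2 CPM relative to the other 3; control replicate 2 is lowest at -0.441 and Usp28 KO replicate 2 highest at 0.451.

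**Figure D3:**
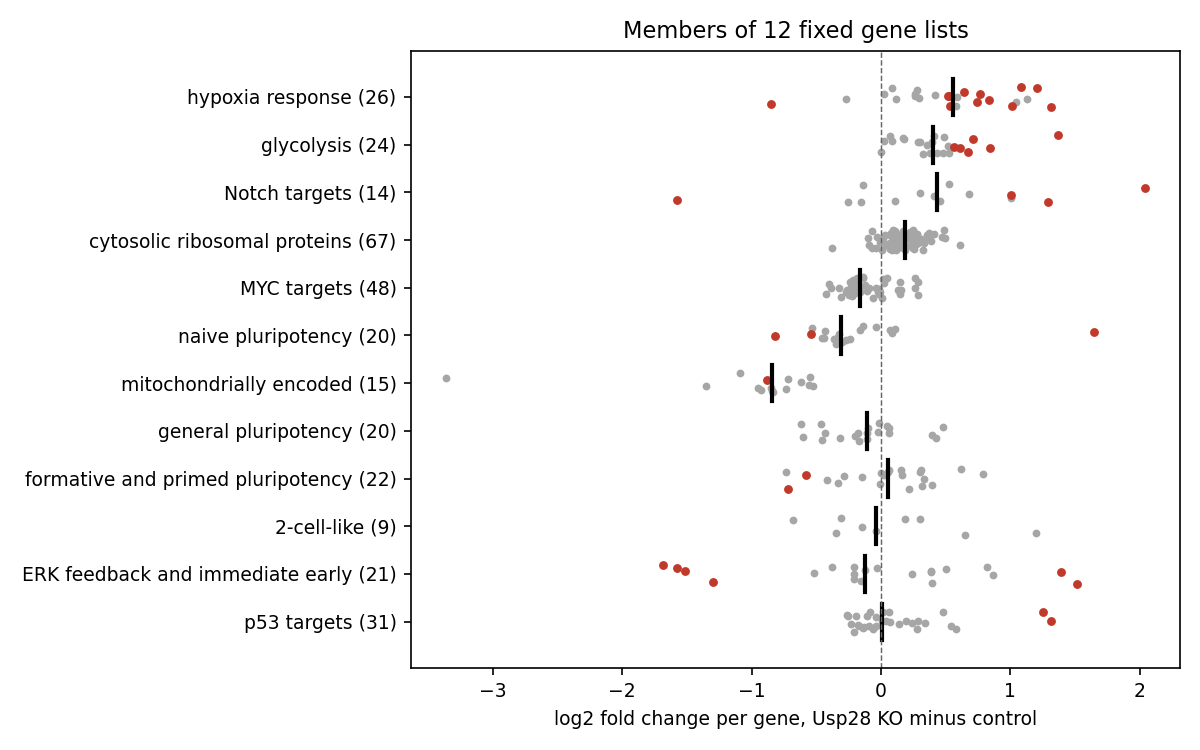
Log2 fold change (Usp28 KO minus control) of each tested member of 12 gene lists. Red points passed adjusted over the list alone, grey points did not, black bars are list medians, and the number of tested members stands beside each name; the hypoxia response and glycolysis lists sit to the right at medians of 0.56 and 0.40, and the mitochondrially encoded list to the left at -0.84.

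The p53 target list did not pass the camera test. Of 31 p53 targets, Ddit4 and the peptide transporter gene Tap1 rose adjusted over the list alone and 29 did not pass (median 0.0054, camera adjusted p = 0.506). Its median was 0.080 without control replicate 1 (adjusted p = 0.102), -0.051 without control replicate 2 (adjusted p = 0.737), -0.088 without Usp28 KO replicate 1 (adjusted p = 0.636) and 0.15 without Usp28 KO replicate 2 (adjusted p = 0.0181). Cdkn1a was at 120.2 ± 20.6 CPM in control and 117 ± 3.31 CPM in Usp28 KO libraries, and Mdm2 and Bbc3 had log2 fold changes of -0.040 ± 0.16 and 0.58 ± 0.19. After GC correction the Bbc3 log2 fold change was 0.37. Other lists that did not pass camera, with 0 members past the list-alone test, included the integrated stress response and unfolded protein response (median 0.089, adjusted p = 0.269), heat shock (-0.093, adjusted p = 0.656), cholesterol synthesis (0.20, adjusted p = 0.0701), lysosome and autophagy (0.026, adjusted p = 0.999), G1/S and DNA replication (-0.015, adjusted p = 0.888), mitosis (-0.11, adjusted p = 0.0514) and replication-dependent histones (0.32 over 5 tested members, adjusted p = 0.896). For the histones, poly(A) selection leaves few reads, as most of these transcripts lack a poly(A) tail. Over all settings the median of the integrated stress response list ran from 0.0021 to 0.19. The cholesterol median was 0.28 without control replicate 1 (adjusted p = 0.0129), 0.12 without control replicate 2 (adjusted p = 0.521), 0.0019 without Usp28 KO replicate 1 (adjusted p = 0.990) and 0.27 without Usp28 KO replicate 2 (adjusted p = 0.00129). The mitosis median was -0.14 without Usp28 KO replicate 1 (adjusted p = 0.0255). The heat shock median was -0.041 without control replicate 1 (adjusted p = 0.971), and that of the integrated stress response list was 0.19 without control replicate 1 (adjusted p = 0.0943) and 0.14 without Usp28 KO replicate 1 (adjusted p = 0.0941).

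Lineage lists held single genes that moved. In the neuroectoderm list, Nes (20.4 ± 1.80 to 48.9 ± 7.01 CPM) and the RNA-binding protein genes Elavl3 and Msi1 rose adjusted over the list alone and 12 did not pass (median 0.0034, camera adjusted p = 0.506). In the mesendoderm and mesoderm list, Cdx1, Snai1 and Nkx1-2 fell and 9 did not pass (median -0.24, adjusted p = 0.109). That median was 0.12 without control replicate 1 (adjusted p = 0.971), -0.39 without control replicate 2 (adjusted p = 0.0266) and -0.14 without Usp28 KO replicate 1 (adjusted p = 0.694). T was at 1.75 ± 0.341 CPM in control and 1.79 ± 0.268 CPM in Usp28 KO libraries. In the trophectoderm list the homeobox gene Esx1 rose from 1.57 ± 0.190 to 6.76 ± 2.02 CPM (list-alone adjusted p = 0.000582) and 13 did not pass (median 0.076, adjusted p = 0.175). That median was 0.20 without control replicate 1 (adjusted p = 0.451), 0.34 without control replicate 2 (adjusted p = 0.119), 0.33 without Usp28 KO replicate 1 (adjusted p = 0.0598) and 0.19 without Usp28 KO replicate 2 (adjusted p = 0.346). Cdx2 was at 0.0512 ± 0.0724 CPM in control and 0 ± 0 CPM in Usp28 KO libraries. In the primitive endoderm list the collagen chaperone gene Serpinh1 rose from 14.5 ± 3.71 to 30.1 ± 5.31 CPM and 13 did not pass (median 0.0076, adjusted p = 0.999), and Gata6 was at 1.20 ± 0.623 CPM in control and 1.44 ± 0.601 CPM in Usp28 KO libraries. Among epithelial and mesenchymal genes, the tight junction genes Cldn7, Tjp3, Cldn6 and Cldn3 rose and Snai1, a repressor of epithelial genes, fell, adjusted over the list alone, and 19 of 24 did not pass (median 0.14, adjusted p = 0.0701). That median was 0.19 without control replicate 1 (adjusted p = 0.0452) and 0.23 without Usp28 KO replicate 1 (adjusted p = 0.0306). Snai1 was low in both groups, at 0.699 ± 0.0970 CPM in control and 0.0801 ± 0.0376 CPM in Usp28 KO libraries. Of 11 tested fibroblast feeder cell markers, Mmp2 rose and 10 did not pass (median 0.16, adjusted p = 0.291; 0.10 without Usp28 KO replicate 2, adjusted p = 0.970).

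Imprinted genes moved in both directions. The amino acid transporter gene Slc38a4 (chromosome 15, 96994820 to 97055956) rose from 34.96 ± 2.82 to 75.6 ± 19.2 CPM and Sgce rose by 0.74, while Zdbf2 fell from 181 ± 10.5 to 105 ± 1.25 CPM and Plagl1 (chromosome 10, 13060504 to 13131694) fell from 121 ± 27.5 to 46.6 ± 19.4 CPM, adjusted over the list alone; 29 did not pass (median 0.0087, camera adjusted p = 0.703). In the DNA methylation machinery list, Dppa3 rose and 17 did not pass (median -0.060, adjusted p = 0.738). The germline list had a median of 0.38 with 0 of 23 past the list-alone test (adjusted p = 0.0701; adjusted p = 0.796 with an estimated correlation). It was 0.47 after GC correction (adjusted p = 0.00343), 0.20 without control replicate 1 (adjusted p = 0.775) and 0.56 without control replicate 2 (adjusted p = 0.00362). In the interferon response list, the antigen presentation genes H2-K1, H2-D1 and Tap1 and the antiviral gene Bst2 rose, the RNA sensor gene Ddx58 and Irf9 fell, and 10 did not pass (median 0.086, adjusted p = 0.301). That median was -0.0073 without control replicate 1 (adjusted p = 0.600), 0.26 without control replicate 2 (adjusted p = 0.132), 0.21 without Usp28 KO replicate 1 (adjusted p = 0.103) and 0.16 without Usp28 KO replicate 2 (adjusted p = 0.241). H2-K1 went from 7.71 ± 0.0254 to 17.05 ± 4.79 CPM; it and H2-D1 have paralogs of similar sequence. The median, the mean and the camera direction differed in sign for the formative and primed pluripotency, 2-cell-like, primitive endoderm, WNT, DNA methylation machinery, heat shock and lysosome and autophagy lists, none of which passed.

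Reads of the Y-linked genes Ddx3y, Eif2s3y, Uty and Uba1y were seen in the control group and not in the libraries labelled Usp28 KO. They were few in control too. There Ddx3y had 0.0920% of the reads of its X-linked partner Ddx3x, and Eif2s3y 0.487% of those of Eif2s3x. Some other chromosome Y genes had reads in both groups (Gm47283: 1692 and 553 reads in control replicates 1 and 2, and 610 and 1959 in Usp28 KO replicates 1 and 2). Reads of pseudogenes and of genes with an X copy can come from elsewhere, so these do not show a Y chromosome. Ddx3y (chromosome Y, 1260771 to 1286629) had 14 and 13 reads in control replicates 1 and 2, Eif2s3y (chromosome Y, 1010543 to 1028847) 23 and 12, Uty 10 and 2, and Uba1y 2 and 0. All 4 had 0 in both libraries labelled Usp28 KO, and Kdm5d had 0 in all 4 libraries. As CPM of the raw library totals, together they stood at 2.10 in control and at no more than 0.0817 in the libraries labelled Usp28 KO by the limit of 3 counts over the group, at least 25.7-fold lower (exact binomial test against the library totals, two-sided, p = 7.23e-24, over reads of these libraries rather than over cultures). Adjusted over their list alone, Eif2s3y and Ddx3y fell, and Xist and Tsix did not pass. Xist was at 5.88 ± 0.865 CPM in control and 3.85 ± 0.672 CPM in Usp28 KO libraries. Across chromosomes, camera called M (23 genes, shift -0.84, adjusted p = 1.02e-09) and Y (5 genes, shift -3.56, adjusted p = 0.00124), each with an adjusted p = 0.657 with an estimated correlation. The Y shift is a median over 5 genes and is set by Mid1-ps1, with a log2 fold change of -3.56 and 1 read in each Usp28 KO library. Eif2s3y and Ddx3y, at 0 counts in those libraries, lie below it, and Gapdh-ps15 and Gm47283 above it. It is therefore not a bound. Without control replicate 1, control replicate 2 or Usp28 KO replicate 1, 1 chromosome in place of 2 passed. With all libraries no other chromosome passed, and the largest shift among them was 0.0821, of chromosome 15.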

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

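The GC correction, alone and with the replicate block, was chosen after seeing the data. Usp28 kept its direction and stayed above the threshold of 0.05 under all 16 alternatives. Its log2 fold change was -0.043 with library totals alone and -0.048 with upper-quartile scaling, against -0.11 in the main fit. The count of genes by edgeR stayed at 0 each way with DESeq2 size factors, the filter of 50 counts, glmTreat, limma-voom and the GC correction. It was 79 higher and 48 lower with DESeq2, 18 and 3 with upper-quartile scaling, 24 and 5 with library totals alone, 204 and 118 with no filter, and 4 and 3 with the abundant genes removed. Leaving out a library gave 49 to 146 higher and 31 to 200 lower, with the lone library of a group assumed to vary like the others. The cause of these moves was not tested. The labels state no common batch for same-numbered libraries, but their deviations from the group means correlated at 0.354. With the number as a block, the edgeR coefficient of variation between libraries fell from 16.1% to 9.91%. With that block edgeR called 965 higher and 716 lower (978 and 1264 with the GC correction and the block). Whether the number stands for a real pairing cannot be told from the labels.

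The number of lists past the threshold was 7, between 6 and 9 under scaling, block, stricter filter, removal of abundant genes and GC correction, 14 with no filter, 5 to 10 with a library left out, and 0 with an estimated correlation or fry. Chromosomes past it were 2, 0 with an estimated correlation, 1 with the filter of 50 counts and 1 to 2 with a library left out. Log2 fold changes that changed sign, all short of the threshold, were these for genes: with library totals alone, Ccne1 0.037, Cdkn1a 0.025, Mdm2 0.023, Pou5f1 0.039, Usp25 0.062, Zscan4c 0.030; with upper-quartile scaling, Ccne1 0.034, Cdkn1a 0.018, Mdm2 0.017, Pou5f1 0.036, Usp25 0.057, Zscan4c 0.021; with GC correction and replicate block, Klf4 -9.6e-05, T -0.0087, Usp25 0.028, Zscan4c 0.074; with GC correction, T -0.017, Usp25 0.028, Zscan4c 0.055; with the filter of 50 counts, Usp25 0.014; with limma-voom, Zscan4c 0.030. For list medians they were: with GC correction, 2-cell-like 0.086, LIF and STAT3 targets -0.12, lysosome and autophagy -0.0072, neuroectoderm -0.0057, primitive endoderm -0.078, trophectoderm -0.00031; with GC correction and replicate block, 2-cell-like 0.085, LIF and STAT3 targets -0.13, neuroectoderm -0.039, primitive endoderm -0.077; with library totals alone, 2-cell-like 0.030, G1/S and DNA replication 0.045, USP28 and FBXW7 axis 0.0055; with no filter, 2-cell-like 0.13, imprinted -0.069, mesendoderm and mesoderm 0.034, p53 targets -0.016; with upper-quartile scaling, 2-cell-like 0.021, G1/S and DNA replication 0.042, USP28 and FBXW7 axis 0.0015; with the filter of 50 counts, imprinted -0.056; with DESeq2 size factors, neuroectoderm -0.0018; with the abundant genes removed, neuroectoderm -0.0063, p53 targets -0.0035, primitive endoderm -0.0021. With a library left out, values of either sign ran from lowest to highest as follows: Ccne1 -0.18 to 0.11, Cdkn1a -0.21 to 0.14, Dnmt3b -0.34 to 0.065, Esrrb -0.38 to 0.021, Gata6 -0.26 to 0.92, Klf4 -0.13 to 0.32, Mdm2 -0.13 to 0.039, Nanog -0.26 to 0.051, Otx2 -0.24 to 0.43, Pou5f1 -0.21 to 0.18, Sox2 -0.035 to 0.13, T -0.17 to 0.24, Usp25 -0.13 to 0.11, Zscan4c -0.43 to 0.44, Zscan4d -0.73 to 1.34, 2-cell-like -0.38 to 0.57, DNA methylation machinery -0.10 to 0.014, ERK feedback and immediate early -0.12 to 0.017, G1/S and DNA replication -0.063 to 0.036, LIF and STAT3 targets -0.13 to 0.23, WNT targets -0.16 to 0.0055, formative and primed pluripotency -0.064 to 0.080, imprinted -0.020 to 0.10, interferon response -0.0073 to 0.26, lysosome and autophagy -0.081 to 0.064, mesendoderm and mesoderm -0.39 to 0.12, neuroectoderm -0.12 to 0.0033, oxidative phosphorylation -0.062 to 0.23, p53 targets -0.088 to 0.15, primitive endoderm -0.24 to 0.11, replication-dependent histones -0.21 to 1.10. Genes that kept their sign and moved over 1.5 times were: Dppa2 -0.96 to -0.35, Elavl3 0.68 to 1.53, Mycn -0.14 to -0.0091, Notch1 0.19 to 0.40, Rplp2 0.079 to 0.81, Rps20 0.24 to 0.49, Rps29 0.16 to 0.95, Tcl1 -0.80 to -0.31, Tsix -0.85 to -0.34, mt-Co1 -0.996 to -0.12, mt-Rnr1 -0.89 to -0.13, mt-Rnr2 -1.21 to -0.45. The cause was not tested.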

Other observations

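The fits that leave out a library were planned; the other tests in this part were chosen after the results they bear on were seen.

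Some genes were called by edgeR in each of the 4 fits with a library left out. Among them were Etv1, Etv4 and Spry4 (lower), and Ier3, Ddit4, Eno2, Nes, Dll1, Dppa3 and Bhlhe41 (higher). The fits share libraries, so these calls are not independent of each other.

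Higher hypoxia response and glycolysis lists. A GC trend between libraries was tested first: with GC-corrected offsets the medians were 0.561 for hypoxia response and 0.319 for glycolysis, each past the threshold, which argues against that trend as the whole cause. A single library as the cause was tested by leaving out each: the lowest medians were 0.323 and 0.329, also past the threshold. Loss of Usp28, a difference between clones, and a difference in cell density or oxygen between cultures all coincide with the groups and stay open, untested. Any of these may contribute. The call itself is lost when the correlation between members is estimated (adjusted p = 0.796 for each list). The call is also lost with fry, and both settings called 0 lists. Their power with 2 libraries per group was not measured, so these losses do not decide the question. The preset correlation was not tested on members that vary together.

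Reads of 4 Y-linked genes absent from the libraries labelled Usp28 KO. Lower depth is argued against, since 77.2 reads of the 4 genes were expected at the control rate and 0 were seen. Male fibroblasts in the control libraries are argued against by Col1a1, Col1a2 and Col3a1, from the marker list drawn up in advance: they had 10 reads in control and 13 in Usp28 KO libraries, a control to Usp28 KO ratio in CPM of 0.782 (95% interval 0.307 to 1.93), fewer in control than the 76 Y-linked reads. Cells without the Y chromosome remain a candidate explanation. Other Y genes with at least 10 reads cannot decide it, since reads of pseudogenes and of genes with an X copy can come from elsewhere. Of 4 such genes, 1 was lower (Mid1-ps1, 25 reads against 2, ratio 0.0787). Gapdh-ps15, Gm20775 and Gm47283 were not (Gm47283 had 1692 and 553 reads in control and 610 and 1959 in Usp28 KO libraries). Even in control, Ddx3y had 0.0920% of the reads of its X-linked partner Ddx3x, and Eif2s3y 0.487% of those of Eif2s3x, so a minority of cells with a Y chromosome in the control culture may be the source, which was not tested.

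Lower mitochondrially encoded list. Control replicate 2, with the highest mitochondrial share, may be the source of much of the shift: without it the median was -0.0816, against -0.84 with all libraries. Replicate 2 had the higher share in both groups, however. Between same-numbered libraries the share was lower in Usp28 KO each time (2.77% and 1.92% for number 1, 5.65% and 3.33% for number 2). Leaving out control replicate 2 does not separate that library from a difference between the numbers. The median also moved without the others, to -1.35 without control replicate 1, -0.49 without Usp28 KO replicate 1 and -1.44 without Usp28 KO replicate 2, each past the threshold. A GC trend as the whole cause is argued against, since the median was -0.499 and past the threshold after GC correction, but it was smaller than before, so that trend may be part of the cause. The call is lost when the correlation between members is estimated (camera, adjusted p = 0.796) and with fry. Both settings called 0 lists, and their power at 2 libraries per group was not measured. Loss of Usp28 was not tested apart from these.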
